A study of Arabidopsis thaliana with 4 samples.

How the data were processed

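The series followed MM2d, a suspension-cultured cell line of Arabidopsis thaliana, through a growth course. Per the labels' protocols, 5 ml of a culture in early stationary phase, 7 days after its previous subculture, was diluted into 100 ml of new medium holding 3% sucrose, 0.5 mg/l of the auxin NAA and 0.05 mg/l of the cytokinin kinetin. The flasks turned at 130 rpm and 27 °C in the dark, and cells were collected on days 1, 3, 5 and 7. Total RNA of each day was labelled with biotin and hybridised to 1 Affymetrix ATH1 array, so each of the 4 days is 1 group of 1 array.

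The deposited values are signal intensities on a linear scale, 1 per probe set and array, made with MAS5 per the submitters' processing notes; its version is not given in the sources used here. MAS5 combines the perfect-match and mismatch probes of a probe set into 1 signal and scales each array by a constant. In the deposited table the mean signal, with 2% of the values trimmed at each end, was 100.0 on every array, so the arrays were compared as deposited. Such scaling sets the total signal equal on all arrays, and a change in the RNA content of the cells leaves no trace in it. The table holds 22810 probe sets, of which 64 control probe sets were left out of the comparisons. It gives no detection calls, and MAS5 signals near 0 have a large relative error, with values down to 0.0191 here. A floor was therefore set at the 40th percentile of all signals, 25.26. A lower signal was raised to the floor and read as a bound, so a ratio against it is written as at least N-fold. A probe set was called measured where at least 1 array lay above the floor, which held for 15292.

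Genes were named from the platform's annotation table given with the values and from RefSeq's gene table for assembly TAIR10.1. The annotation table lists 14016 of the probe sets, 13513 with 1 gene and 503 with several, and leaves 8730 unnamed here. Of the probe sets with 1 gene, 1579 carry a symbol other than a locus code and 13436 matched the RefSeq table. Probe sets of several genes were given no name. Genes known here only by a locus code are printed by that code. No coordinates are given, since the build behind the array's annotation is not given in the sources used here.

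With 1 array per day there is no replicate error, so 2 days could not be tested against each other, and a trend over the 4 days was not fitted. Each of the 4 comparisons (day 3 against day 1, day 5 against day 3, day 7 against day 5 and day 7 against day 1) counts measured probe sets at least 2-fold higher or lower. The size of measurement error was gauged from 96 genes with 2 measured probe sets, whose log2 ratios should be equal. Error shared by both probe sets of a gene, such as a difference between cultures or labellings, cancels in this measure and is left out. Gene groups were described by the median log2 ratio of their measured genes, each gene being the mean over its own probe sets. A group's median was ranked among 10000 random lists of the same size, matched on mean log2 signal in 20 bins (seed 7). It is said to stand apart below the 2.5th or above the 97.5th percentile, which describes these arrays and is no test over replicates. A list needed at least 4 measured genes. The day of highest and lowest signal was counted among probe sets with at least a 2-fold range over the 4 arrays.

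Before the data were examined, 33 lists with 588 genes were fixed, but only 98 of these genes have a probe set that the annotation gives to that gene alone. That left 6 of the 33 lists with enough genes: core histones (the 7 measured genes all encode H2B), ribosome biogenesis, autophagy, sugar starvation, senescence with vacuolar proteolysis, and wall loosening. After the annotation had been seen, and before any gene's signal was examined, 26 lists with 617 members were added, of which 25 had enough genes. Of these members, 186 were chosen by locus code from general knowledge of the cytosolic ribosomal protein, class III peroxidase and low-oxygen genes. Some genes stand in both a planned and an added list. In all 31 lists were ranked in 4 comparisons, 124 rankings. Were the lists drawn at random, 1.55 per comparison would lie outside the limits. Members of a real list can vary together and some lists overlap, so 1.55 is no rate of false calls.

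Genes named in the text follow a rule fixed before the data were examined. For each comparison it takes the 10 largest differences in each direction among probe sets above the floor on both arrays, at least 2-fold, naming 1 gene with a symbol and lacking a suffix for cross-hybridisation; 1121 probe sets were eligible. It adds the 3 largest differences in each direction from or to below the floor, and from each list up to 4 members with the largest difference, or all members of lists of at most 8 genes. A member outside the rule is named as an exception or because its group is described by it.

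The counting and ranking steps were tested on simulated arrays with the error estimated from genes with 2 probe sets. The probe sets given a 3-fold or 4-fold change were bright, more than 3 log2 units above the floor on all 4 arrays. Recovery among dimmer probe sets was therefore not tested. For day 3 against day 1, 96 of 100 probe sets changed 4-fold and 89 of 100 changed 3-fold were recovered, for day 5 against day 3, 100 and 97, for day 7 against day 5, 100 and 97, and for day 7 against day 1, 91 and 78. Of 200 lists with no change, 7, 11, 9 and 5 fell outside the limits in the same 4 comparisons. Their genes were drawn at random and given independent error, so a share near that set by the limits was built in. Lists whose members vary together were not simulated.

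Alternatives fixed before the data were examined were 3 other scalings (a common median, a common 75th percentile, quantile normalization), other floors (the 25th percentile, the 50th percentile, none), limits of 1.5-fold and 3-fold, leaving out dim probe sets, leaving out cross-hybridising probe sets, and the brightest probe set in place of the mean. Scaling to the 17 hybridisation control probe sets was added after seeing the data. Calculations used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.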

Results

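MM2d cells were profiled on ATH1 arrays 1, 3, 5 and 7 days after dilution of an early stationary culture into new medium. There was 1 array per day and no replicate, so every difference given is that between single arrays. Of 22746 probe sets, 12976 (57.0%) lay above the floor on day 1, 13720 (60.3%) on day 3, 13873 (61.0%) on day 5 and 14021 (61.6%) on day 7. The median signal was 36.3, 41.4, 43.2 and 44.3 on the 4 days. The ratio of 3' to 5' signal, a measure of RNA integrity, was 1.45, 1.09, 1.18 and 1.05 for actin, 0.979, 0.950, 0.996 and 1.12 for GAPDH, and 1.59, 1.22, 1.3 and 1.24 for ubiquitin. SAND and TIP41, often used as reference genes, had log2 ratios of 0.06 and 0.25 between days 7 and 1.

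Over the whole course, transcripts for cytosolic ribosomal proteins became less abundant from day to day, and those for ribosome assembly were less abundant on day 7 than on day 1. Class III peroxidases, several ATG8 autophagy genes and the 4 measured genes of the senescence list were more abundant at the end, though the autophagy list did not stand apart after quantile normalization. The median of the low-oxygen genes was high on day 3 and near its first level on days 5 and 7. The median log2 ratio of the 111 ribosomal protein genes to day 1 was -0.28 on day 3, -1.04 on day 5 and -1.55 on day 7, and that of the 21 peroxidase genes was 0.45, 0.51 and 1.51, the last being 0.71 with the floor at the 25th percentile. Among 4779 probe sets with at least a 2-fold range, 1518 were highest on day 1, 677 on day 3, 787 on day 5 and 1797 on day 7. The lowest signal fell on day 1 for 1796, on day 3 for 616, on day 5 for 394 and on day 7 for 1647, with 326 tied at the floor. Days 1 and 7 cannot be ranked by these counts. With a common median 2529 were highest on day 1 and 1267 on day 7, with a common 75th percentile 1934 and 1543, after quantile normalization 1672 and 1549, and with the hybridisation controls 1077 and 3633. The lowest signal fell on day 1 and on day 7 for 1079 and 2370, 1433 and 1937, 1374 and 1762, and 2405 and 771 with these scalings.

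**Figure D1:**
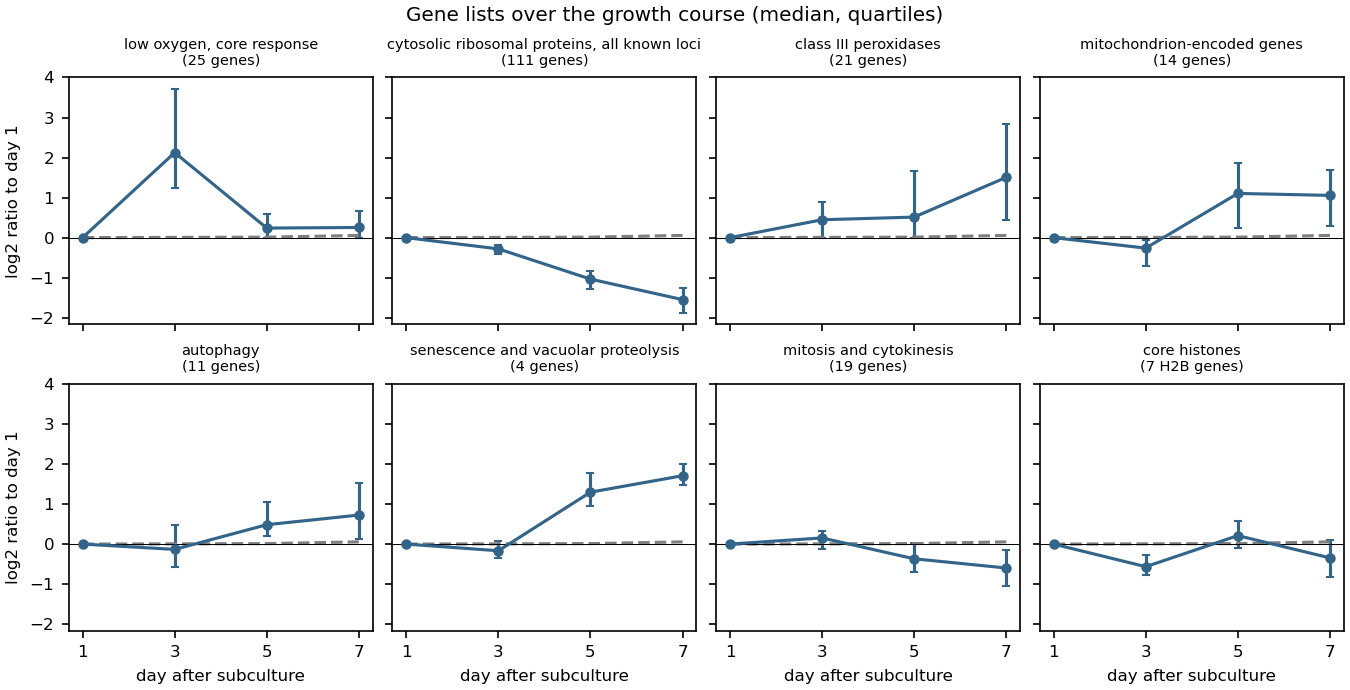
Median log2 ratio to day 1 (vertical axis) of 8 gene lists by day after subculture (horizontal axis), with bars from the lower to the upper quartile of the genes and a dashed line for the median of all 8541 measured genes. The low-oxygen list reaches 2.12 on day 3 and 0.24 on day 5, while the ribosomal protein list lies at -1.55 on day 7.

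Day 3 against day 1 set the culture beside its newly diluted state. Genes of the core low-oxygen response, which plant cells switch on when oxygen runs short, were far more abundant on day 3. Of the 25 measured, 19 were at least 2-fold higher and 0 at least 2-fold lower, with a median log2 ratio of 2.12 (quartiles 1.24 and 3.72), above all 10000 random lists, whose central 95% ran from -0.10 to 0.28. AT4G27450 had a signal of 32.2 on day 1 and 1377 on day 3, a 42.8-fold difference. AT1G33055, at 1243 on day 3, was at least 49.2-fold higher, AT3G29970 at least 22.0-fold and AT5G66985 at least 16.4-fold.

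PDC2, a pyruvate decarboxylase of ethanol fermentation, was 2.80-fold higher on day 3, with a signal of 205 on day 1 and 573 on day 3. HRA1, a transcription factor that restrains the low-oxygen response, was 4.36-fold higher and CML38, a calmodulin-like protein, 4.16-fold. LDH1, lactate dehydrogenase, had a log2 ratio of 0.05 and AT3G10020 one of -0.14. The low-oxygen list was among those added after the annotation had been seen, and how the day 3 cells were handled at collection is not given in the sources used here.

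**Figure D2:**
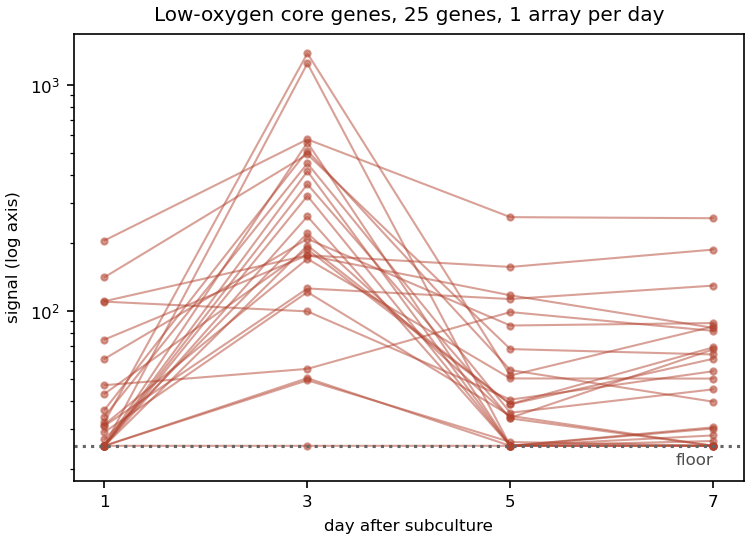
Signal on a log axis (vertical) of the 25 measured low-oxygen genes by day after subculture (horizontal), 1 line per gene and 1 array per day, with signals below the floor of 25.26 (dotted) drawn at it. AT4G27450 lies at 32.2, 1377, 51.7 and 85.2 on days 1, 3, 5 and 7.

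Class III peroxidases, secreted enzymes that act on the cell wall, were also more abundant on day 3, with a median log2 ratio of 0.45 (quartiles 0.00 and 0.90) and 5 of 21 genes at least 2-fold higher. PRX52 had a log2 ratio of 1.07, and Prx37 was 2.88-fold higher. Serine carboxypeptidase-like genes had a median of 0.46, outside the random lists' range of -0.18 to 0.24, with scpl48 3.38-fold higher; without the floor this list no longer stood apart. The 19 plastid-encoded genes for gene expression had a median of 0.43 with 5 at least 2-fold higher, among them rpl36 (log2 ratio 1.55), rpl14 (1.34) and rpl16 (1.31), all proteins of the plastid ribosome.

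The 43 plastid-encoded photosynthesis genes went the other way, with a median of -0.43 and 33 below 0, among them psbN (-1.51), ndhE (-1.21) and ndhJ (-1.09), while atpB was higher (1.07). The 7 measured core histone genes, all of histone H2B, had a median of -0.56 (quartiles -0.78 and -0.27), below the random range of -0.33 to 0.45, with 6 below 0 but none at least 2-fold lower; HTB3 was at -0.99 and HTB11 at -0.88. Cytosolic ribosomal protein genes had a median of -0.28, below 0 in 101 of 111, and AT2G19740 (-1.16) and AT3G06700 (-1.15) were the only 2 at least 2-fold lower. Nuclear RNA polymerase subunits had a median of -0.30, which did not stand apart after quantile normalization, and NRPA1, the largest subunit of RNA polymerase I, was at -0.63. The 14 mitochondrion-encoded genes had a median of -0.26, which did not stand apart without cross-hybridising probe sets. Nuclear photosynthesis genes, taken as markers of green cells, had a median of -0.20, which did not stand apart with arrays scaled to a common median or to the hybridisation controls.

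Outside these groups, CaS, a calcium-binding thylakoid protein, was 5.09-fold higher on day 3, AILP1 4.80-fold, and FDH, formate dehydrogenase, 4.17-fold. The tetraspanin TET5 had a signal of 43.1 on day 1 and 185 on day 3, and FHL, which carries phytochrome A into the nucleus, a log2 ratio of 2.07. The kinase FU was 3.34-fold and the SUMO ligase SIZ1 3.25-fold higher by the probe set named, while another probe set of each gave log2 ratios of 0.05 and 0.98. MYBC1 was at least 6.20-fold, the pectin methylesterase PMEPCRF at least 4.38-fold and TET2 at least 4.00-fold higher. Lower on day 3 were the beta-glucosidase BGLU28 (4.24-fold, signal 2368 on day 1), AGL28 (4.12-fold), FOLB2, a folate synthesis enzyme (3.49-fold), UGT73D1 (2.72-fold), SECE1, part of the thylakoid Sec translocase (2.59-fold), and NDB2, an alternative NADH dehydrogenase of mitochondria (2.06-fold). For chr31 the log2 ratio was -1.45 by the probe set named and at least 0.24 by another. AGL62, YUC6, an enzyme of auxin synthesis, and UGT73B4 were at least 2.48-fold, 2.26-fold and 2.08-fold lower.

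In all, 614 probe sets were at least 2-fold higher and 252 at least 2-fold lower on day 3 (5.66% of those measured), 143 of the former from below the floor. With arrays scaled to a common median the split was 414 higher and 470 lower, after quantile normalization 477 and 311, and with scaling to the hybridisation controls 489 and 318. Of the 31 lists, 4 stood apart upward and 6 downward. Simulated error as large as the disagreement between probe sets of 1 gene (SD 0.57 log2) took 937 of 14705 unchanged probe sets (6.37%) past 2-fold. That SD exceeds the SD of all measured log2 ratios in this comparison, 0.53, which also holds any real change. It is thus too large for a typical probe set, and how many of the 866 are error cannot be said. The SD was 0.57 and 0.64 in the comparisons with day 1, and 0.36 and 0.30 in those without it. Whether the day 1 array carries more error than the others was not tested. A single gene's ratio here carries little weight. Of 26 changed probe sets with a partner for the same gene, 21 had the partner on the same side of 0 and 4 had it at least 2-fold different too.

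Day 5 against day 3 covered the middle of the course. Low-oxygen genes were low again, mitochondrion-encoded transcripts were more abundant as a group, and autophagy genes and the 4 measured genes of the senescence list were higher, while cytosolic ribosomal protein genes were lower. Of the 25 low-oxygen genes 18 were at least 2-fold lower on day 5 (median log2 ratio -2.28, quartiles -3.44 and -0.99), 17 of them among the 19 that had been at least 2-fold higher on day 3. AT4G27450 had a signal of 51.7 on day 5, HRA1 38.6 and PDC2 260, and AT5G42200 stayed at 113 after 126 on day 3. Since both ratios share the day 3 array, an error of that array alone would move a gene up and then down.

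The 14 mitochondrion-encoded genes had a median log2 ratio of 1.32 (quartiles 0.67 and 2.07), above all random lists, and 9 were at least 2-fold higher, while ccb206 (0.05), nad1 (0.27) and nad6 (0.30) lay within the error between probe sets. Among the 9 were nad9, a subunit of respiratory complex I (signal 38.7 on day 3 and 232 on day 5), ccb382, which acts in cytochrome c maturation (5.92-fold), and the cytochrome oxidase subunits cox1 (3.73-fold) and cox2 (3.57-fold). A large copy of the mitochondrial genome lies in the nuclear genome, and probe sets cannot separate the copies. The nuclear genes of the tricarboxylic acid cycle had a median of -0.40, within the random lists' range. Plastid-encoded photosynthesis genes had a median of 0.62 with 9 of 43 at least 2-fold higher, led by psbN (2.44), psbA (2.04) and atpH (1.63). The plastid's genes for gene expression again went the other way, with a median of -0.60; rps19 and rps4 were 3.54-fold and 3.41-fold lower, rpl36 was at -1.85 log2 and rpl20 had a log2 ratio of 1.38. The median log2 change of the 3' to 5' ratios between these arrays was 0.10.

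All 4 measured genes of the senescence and vacuolar proteolysis list were higher on day 5 (median 1.65, random range -0.57 to 0.72). SAG101, a senescence-associated gene, was 4.01-fold higher, GAMMA-VPE, a vacuolar processing protease, 3.93-fold, and the transcription factor WRKY6 was at 1.32 log2, while WRKY53 was at least 1.78-fold higher. All 11 autophagy genes lay above 0 (median 0.64, quartiles 0.31 and 0.96), with ATG8F, which coats the forming autophagosome, 2.86-fold, ATG1A, a kinase that starts the process, at 1.03 log2 and ATG8E 2.01-fold higher. The H2B genes had a median of 0.62, with HTB3 3.13-fold and HTB2 2.11-fold higher and HTB5 at a log2 ratio of -0.01.

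Among cytosolic ribosomal protein genes, 109 of 111 lay below 0 on day 5 against day 3 and 21 were at least 2-fold lower (median -0.75, quartiles -0.94 and -0.55, random range -0.42 to -0.16), led by AT5G59240 (-1.60) and AT5G57290 (-1.43). Mitosis and cytokinesis genes had a median of -0.42, with 16 of 19 below 0; BUB3.1, of the spindle checkpoint, was 2.60-fold lower and AUR3, an Aurora kinase, was at -0.90 log2. Dehydrins and LEA proteins had a median of -0.98 over 4 genes, with DI21 3.25-fold and COR47 2.76-fold lower, LEA26 at -0.49 and LEA27 at -0.07; with the floor at the 25th percentile the list did not stand apart.

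Wall genes were split. Class III peroxidases went both ways, with a median of 0.00, 5 genes at least 2-fold higher and 4 lower. The wall-loosening list had a median of 0.53, which did not stand apart without a floor, and all annotated expansins one of 0.32, which did not stand apart without a floor or with one at the 25th percentile. EXLA2 was 4.73-fold higher, while EXPA15 (log2 -2.07) and EXPB3 (-1.56) were lower. Of 5 xyloglucan transglycosylases, enzymes that reconnect wall xyloglucan chains, XTH19 had a log2 ratio of 1.85 and XTH20 one of -1.85; the list's median was 0.66 but -0.03 with the floor at the 50th percentile, where it did not stand apart, nor did it with scaling to the hybridisation controls or with a lower floor or none. Beta-glucosidases had a median of 0.26, which did not stand apart after quantile normalization, with a floor at the 25th percentile or with none; BGLU46 was 4.71-fold and BGLU28 3.39-fold higher.

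Also higher on day 5 were ycf3, a plastid gene for photosystem I assembly (6.51-fold), PMEPCRF (4.35-fold), FMO (4.33-fold), the signalling peptide gene CLE44 (4.33-fold) and AAE15, an acyl-activating enzyme (4.18-fold). SWEET10, a sugar transporter, was at least 8.80-fold, HIS1-3, a linker histone, at least 8.62-fold and ATSPS4F, a sucrose-phosphate synthase, at least 8.01-fold higher. CaS (3.58-fold), CML38 (3.53-fold), GEK1 (3.28-fold) and PR-1-LIKE (3.09-fold) were lower. TET3, the glucosinolate transporter GTR2 and TRM31 were at least 2.57-fold, 2.48-fold and 2.21-fold lower.

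In all, 954 probe sets were at least 2-fold higher and 582 lower on day 5 against day 3. With a 3-fold limit the split was 332 and 126, and with a 1.5-fold limit 2239 and 1948. With arrays scaled to a common median it was 831 and 685, with a common 75th percentile 844 and 683, and with the hybridisation controls 1091 and 464. The lists stood apart upward in 9 cases and downward in 5. Simulated error (SD 0.36 log2 between probe sets of 1 gene) took 78 of 14221 unchanged probe sets (0.548%) past 2-fold. That error leaves out differences between cultures, which 1 array per day cannot show. It therefore does not tell how many of the changed probe sets would recur in another culture. Of 23 changed probe sets with a partner, 22 had it on the same side of 0 and 12 had it at least 2-fold different too. Of the 614 probe sets higher on day 3, 181 (29.5%) were then at least 2-fold lower on day 5. Independent sets would give 23.4, and simulations of error alone on a shared day 3 array gave 36.8. Of the 252 lower, 86 were then higher, against 15.7 and 37.2. These simulations gave every array the same error, from the mean of the SDs of the 2 comparisons (0.57 and 0.36 log2), without a floor. They do not cover a larger error on 1 array, so an excess over error cannot be read from them.

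**Figure D3:**
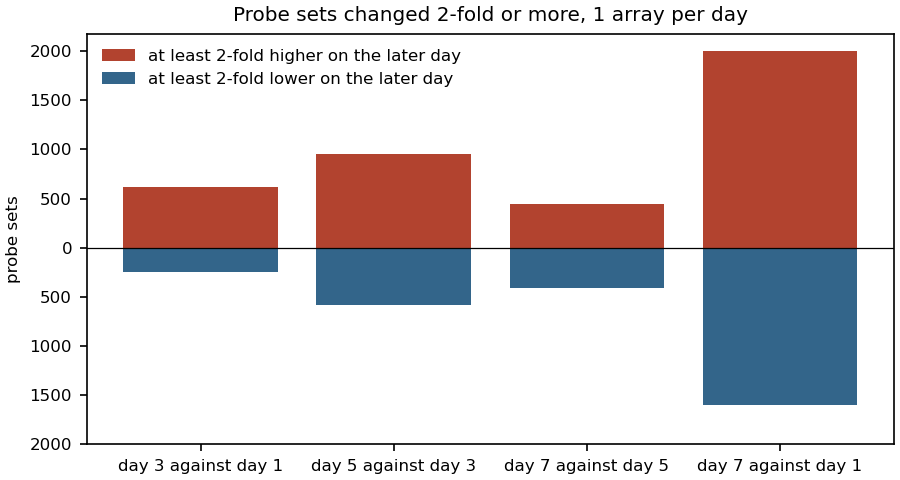
Number of probe sets (vertical axis, from 0 in both directions) at least 2-fold higher (up) or lower (down) on the later day in each of the 4 comparisons (horizontal axis), 1 array per day. Day 7 against day 1 has 1997 higher and 1601 lower, and day 5 against day 3 has 954 and 582.

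Day 7 against day 5 led to the age at which the inoculum had been taken from its own flask, in early stationary phase. Class III peroxidases were more abundant on day 7, and genes of DNA replication, histone H2B, ribosomal proteins and plastid photosynthesis less abundant. Of 21 peroxidase genes 8 were at least 2-fold higher and 0 at least 2-fold lower (median log2 ratio 0.69, quartiles 0.04 and 1.25, above all random lists), with a median of 0.39 with the floor at the 25th percentile. AT5G64120 had a signal of 40.4 on day 5 and 750 on day 7, an 18.6-fold difference, AT5G39580 was 7.55-fold higher and AT2G37130 at least 20.6-fold.

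All 7 genes of the DNA polymerase, primase and chromatin assembly list lay below 0 (median -0.62, quartiles -0.83 and -0.28). PRL, a subunit of the MCM helicase that licenses replication, was 2.27-fold lower, and ICU2, the catalytic subunit of DNA polymerase alpha, 1.74-fold. All 7 H2B genes lay below 0 too (median -0.67), with HTB5 2.68-fold and HTB11 2.07-fold lower. Cytosolic ribosomal protein genes had a median of -0.47, with 104 of 111 below 0 and 7 at least 2-fold lower, among them AT3G06700 (-1.46) and AT5G67510 (-1.41). Nuclear RNA polymerase subunits had a median of -0.40, with NRPC2 of RNA polymerase III at -0.85 and NRPB7 of RNA polymerase II at 1.05.

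Of 43 plastid-encoded photosynthesis genes, 37 lay below 0 on day 7 against day 5 (median -0.48, quartiles -0.67 and -0.36), with ndhF 3.11-fold, atpH 2.32-fold and atpF 2.15-fold lower. The plastid's genes for gene expression had a median of -0.38, with 18 of 19 below 0 and rps15 2.17-fold lower. Nuclear photosynthesis genes had a median of -0.56, with PSBY, of photosystem II, 2.78-fold and ATPC1, of the plastid ATP synthase, 2.26-fold lower and PORB, an enzyme of chlorophyll synthesis, at least 2.52-fold lower. Autophagy genes had a median of 0.32, with 7 of 11 above 0 and none at least 2-fold different; ATG8B was at 0.76 and ATG8E at 0.74.

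Single genes higher on day 7 than on day 5 included XTH18 (6.46-fold), the defensin gene PDF1.4 (5.24-fold), FDH (4.96-fold), the dehydrin COR47 (3.84-fold), WRKY22 (3.69-fold), BGLU46 (3.31-fold), the ubiquitin ligase PUB23 (3.19-fold), the pirin gene PRN (3.03-fold) and GEK1 (2.81-fold), and PWD (AT4G24450) had a signal of 25.4 on day 5 and 117 on day 7. UGT73B4, SFP1, a sugar transporter, and BGLU44 were at least 4.84-fold, 3.51-fold and 2.54-fold higher. Lower were IQD23 (2.44-fold), TBL37 (2.39-fold) and PRP39, a splicing factor (2.39-fold), and AGL28 and BGLU31 were at least 2.49-fold and 2.48-fold lower.

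In all, 449 probe sets were at least 2-fold higher and 415 lower on day 7 against day 5 (5.65% of those measured). With a common median the split was 388 and 441, among brighter probe sets 185 and 235, and with arrays scaled to the hybridisation controls 1178 and 175, since the 17 control probe sets had a median log2 ratio of -0.36 (SD 0.22) between these arrays, and that scaling put the median of all measured probe sets at 0.30. It also put the medians nearer 0, at -0.14 for ribosomal proteins, -0.08 for RNA polymerase subunits and -0.15 for plastid photosynthesis. The medians were -0.05 for plastid gene expression, -0.14 for nuclear photosynthesis, -0.35 for H2B genes and -0.29 for the DNA polymerase list. These lists stayed apart from random lists, but a constant scaling moves random lists by about the same amount, so little else was possible. Of the 31 lists, 2 stood apart upward and 7 downward. Simulated error (SD 0.30 log2) took 5 of 14098 unchanged probe sets past 2-fold. Differences between cultures are left out of that error too, so how many of the changed probe sets would recur cannot be said. All 10 changed probe sets with a partner had it on the same side of 0, and 4 had it at least 2-fold different too.

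Day 7 against day 1 gave the net difference over the course. Transcripts for making ribosomes were less abundant on day 7, at almost every gene measured: 98 of 111 cytosolic ribosomal protein genes were at least 2-fold lower and 0 at least 2-fold higher, with a median log2 ratio of -1.55 (quartiles -1.89 and -1.25), where random lists as bright ran from -0.74 to -0.28; after quantile normalization the median was -1.26. AT3G06700 had a signal of 1416 on day 1 and 134 on day 7 (-3.40 log2), and AT4G30800, AT3G06680 and AT4G10450 had log2 ratios of -2.68, -2.47 and -2.36. The planned members RPL4A, RPL10AB and RPL28A, among the brightest on day 1, were 1.87-fold, 3.15-fold and 3.44-fold lower.

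Ribosome assembly factors lay below 0 in 11 of 11 genes (median -1.19, 6 at least 2-fold lower), among them YAO (3.00-fold) and IMP4 (2.54-fold), both of small-subunit processing. The 4 genes of the planned ribosome biogenesis list, of which PES and RH57 are also among those 11, had a median of -1.24, which did not stand apart with the floor at the 25th percentile or without one; NOP58-2, a core protein of methylation guide complexes, was 2.98-fold and PES 2.43-fold lower, RH57 was at -1.19 and BRX1-1 at -0.96. Nuclear RNA polymerase subunits lay below 0 in 12 of 12 genes (median -0.90), with NRPA1 3.21-fold and NRPC2 2.85-fold lower.

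Genes of mitosis and cytokinesis were lower on day 7 as a group (median -0.60, 15 of 19 below 0, 6 at least 2-fold lower), with a median of -0.28 when arrays were scaled to the hybridisation controls. KINESIN-12B, a motor of the cell plate's forming site, was 2.49-fold lower, AUR2 2.39-fold, AUR1 2.09-fold and HTR12, the centromeric histone, at least 2.33-fold, while ATMAP65-6 was at least 2.18-fold higher. The H2B genes (median -0.34) and the DNA polymerase list (-0.41) did not stand apart over the whole course, though HTB5 had a signal of 123 on day 1 and 30.9 on day 7. Photosynthesis genes of the nucleus had a median of -0.46, which did not stand apart after quantile normalization, and the plastid's own had one of -0.40, which did not stand apart with scaling to the hybridisation controls or with any other floor; psbA had a signal of 145 on day 1 and 768 on day 7, and atpB was higher (2.33). The plastid's genes for gene expression had a median of -0.65, which did not stand apart with scaling to the hybridisation controls or without cross-hybridising probe sets, with rps4 2.45-fold lower.

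Class III peroxidases differed in the opposite direction, with 13 of 21 genes at least 2-fold higher and 0 at least 2-fold lower (median 1.51, quartiles 0.45 and 2.85, above all random lists). With the floor at the 25th percentile the median was 0.71 and without one 0.82, and the list still stood apart. AT1G71695 had a signal of 45.6 on day 1 and 1026 on day 7 (22.5-fold), AT5G17820 was 14.0-fold and PRX52 7.20-fold higher, and AT5G64120 and AT5G39580 were at least 29.7-fold and 24.1-fold higher. All 4 senescence and vacuolar proteolysis genes were higher (median 1.71), GAMMA-VPE 6.57-fold, SAG101 3.17-fold, WRKY53 at least 3.36-fold and WRKY6 1.90-fold. Autophagy genes had a median of 0.73, which did not stand apart after quantile normalization; ATG8E was 8.76-fold, ATG8F 4.97-fold, ATG8A 3.27-fold and ATG8C 2.52-fold higher. The list holds 8 ATG8 genes, of which ATG8G was at -0.65 log2, and of the 3 others ATG4B was at 0.61, ATG1A at -0.13 and ATG3 at -0.39. Mitochondrion-encoded genes stayed high (median 1.06, 7 of 14 at least 2-fold higher), with cox2 5.03-fold and cox1 4.32-fold.

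Among xyloglucan transglycosylases, XTH19, XTH18 and EXGT-A3 were 5.92-fold, 5.88-fold and 5.72-fold higher, XTH16 had a log2 ratio of at least 0.35 and XTH20 was at least 7.93-fold lower. Their median of 2.52 was 0.81 with the floor at the 25th percentile and 0.84 without one, still apart from random lists. Serine carboxypeptidase-like genes had a median of 0.68, with scpl48 6.12-fold higher; the list did not stand apart after quantile normalization, with a floor at the 25th percentile or with none. FDH was 16.7-fold, TET5 10.8-fold, FMO 9.29-fold, LPR2, a multicopper oxidase, 8.70-fold, the auxin-response repressor IAA18 7.60-fold and DI19 6.65-fold higher. BGLU46, PMEPCRF and SWEET10 were at least 23.0-fold, 22.5-fold and 16.9-fold higher. PR-1-LIKE was 5.91-fold, EXPA15 5.22-fold, PPR596 4.48-fold, ndhF 4.48-fold, SK18 4.47-fold, FOLB2 4.36-fold, DECOY 4.31-fold, PRP39 3.74-fold and QQT2 3.62-fold lower, and AGL28 and MPC were at least 12.2-fold and 5.31-fold lower. For chr31 the log2 ratio was -1.90 by the probe set named and at least 0.02 by another.

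In all, 1997 probe sets were at least 2-fold higher and 1601 lower on day 7 against day 1 (23.5% of those measured), 445 of the former from below the floor. With arrays scaled to a common median the split was 1357 and 2491, and with scaling to the hybridisation controls 3291 and 908; these scalings put the median of all measured probe sets at -0.12 and 0.37, against 0.06 as deposited. The 3' to 5' ratios also differed, by a median log2 of -0.36 for day 7 and -0.38 for day 3 against day 1, though GAPDH's was higher on day 7, so differences from day 1 come with a difference in this measure. Of the 31 lists, 6 stood apart upward and 8 downward. Simulated error (SD 0.64 log2 between probe sets of 1 gene) took 1384 of 14824 unchanged probe sets (9.34%) past 2-fold, and of 52 changed probe sets with a partner 43 had it on the same side of 0 and 28 at least 2-fold different too. As for day 3 against day 1, this SD was larger than in the comparisons without day 1. It also leaves out differences between cultures.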

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

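The scaling to hybridisation controls was chosen after the results had been seen, and all other settings before the data were examined. No paired analysis was possible because each day has 1 array. The counts of lists standing apart stayed within 1.5 times in all 36 cases, and the medians of lists kept their direction and side of the limits in 1062 of 1112 cases, with 28 no longer standing apart, 21 newly so and 1 reversed. Of the 47 cases of a list standing apart in a comparison, 46 remained with a common median, 47 with a common 75th percentile, 42 after quantile normalization, 43 with the hybridisation controls, 40 with the floor at the 25th percentile, 45 at the 50th, 39 with none, 45 without cross-hybridising probe sets and 47 with the brightest probe set. Scaling an array by a constant moves a list and its random lists almost alike. The common median, common 75th percentile and hybridisation controls could therefore hardly change a call except near the floor. The brightest probe set could hardly do so either, with 8653 probe sets for 8541 genes. Such cases within the 1062 of 1112 say little about how firm a call is. Xyloglucan transglycosylases on day 5 against day 3 reversed, at -0.032 with the floor at the 50th percentile, which drops a dim member. Named genes kept their value within the spread between probe sets in 658 of 728 cases and list members in 2632 of 2807. The common median, common 75th percentile and quantile normalization moved none of either, their shifts being smaller than that spread. A lower floor or none cannot move a named gene that lay above the floor on both arrays. Such cases say little about how firm a value is.

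Counts of changed probe sets depended most on the floor and the fold limit, by construction. In the order day 3 against day 1, day 5 against day 3, day 7 against day 5 and day 7 against day 1, they were 4080, 4706, 3966 and 7366 without a floor, 2976, 4187, 3076 and 6858 at 1.5-fold, 231, 458, 186 and 1378 at 3-fold, and 461, 874, 420 and 2272 among the brighter probe sets. With the floor at the 25th percentile they were 1434 for day 3 against day 1 and 1391 for day 7 against day 5. Scaling to the hybridisation controls gave 1353 for day 7 against day 5. With 1 array per day and no detection calls, signal near the floor limits what can be counted.

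The days of highest and lowest signal moved with the floor, the scaling and the leaving out of dim probe sets. Without a floor 2745, 2195, 2396 and 3987 probe sets were highest on days 1, 3, 5 and 7, and 4159, 2216, 1860 and 3088 were lowest. Among brighter probe sets 345, 412 and 939 were highest on days 3, 5 and 7, and 1001, 365 and 238 lowest on days 1, 3 and 5. With the hybridisation controls 343, 442 and 3633 were highest on days 3, 5 and 7, and 1190, 675 and 771 lowest on those days. With a common median 2529 were highest and 1079 lowest on day 1. With the floor at the 25th percentile 1048 were highest on day 3 and 662 lowest on day 5. Scaling shifts every probe set of an array alike, and beyond that the cause was not tested.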

Other observations

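The tests of the 3 patterns weighed were chosen after the results had been seen, as was the scaling to the hybridisation controls. The 7 measured sugar starvation genes had medians of -0.10, 0.16, -0.17 and -0.01 in the 4 comparisons (day 3 against day 1, day 5 against day 3, day 7 against day 5, day 7 against day 1), with 0 genes at least 2-fold different in any, the last 2 medians being 0.15 and 0.22 with the hybridisation controls; ETFQO, of branched-chain amino acid breakdown, was at -0.19 and AKINBETA1, a subunit of the SnRK1 kinase, at 0.59 on day 7 against day 1. The wider list for branched-chain amino acid and lysine breakdown had medians of -0.05, -0.12, -0.07 and -0.10, the last 2 being 0.25 and 0.11 with the hybridisation controls. Glycolysis genes had log2 ratios of 0.25 (PGIC), 0.47 (TPI) and 0.15 (GAPC2) over the course, and endoplasmic reticulum folding genes had medians of 0.06, -0.08, 0.16 and 0.13, the first and last being -0.13 and -0.15 with a common median. Medians over the whole course were -0.42 for the tricarboxylic acid cycle, -0.15 for tubulins (0.17 with the hybridisation controls), -0.05 for GH9 endoglucanases (0.25 with them), 0.57 for TBL wall acetyltransferases, 0.28 for UDP-glycosyltransferases, 0.30 for SWEET transporters and 0.14 for AGAMOUS-like genes, none standing apart.

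Lists with too few measured genes are given by member. On day 7 against day 1, HCT, an enzyme of lignin precursor synthesis, was 4.23-fold higher, COB, of cellulose microfibril orientation, 2.35-fold and the starch branching enzyme SBE2.2 at 1.05 log2. In the same comparison AUR3 was at -0.45 log2, FEN1 at -0.16, APL3 at 0.35, UPOX at -0.61, the nitrate transporter NRT2.5 at 0.34, CRT2 at 0.61 and the hormone-response gene LBD16 at 0.16, while IAA20 rested on a day 1 signal and ARR15 on a day 7 signal below the floor. HSP17.6C, a small heat shock protein, was 3.69-fold lower on day 3 than on day 1. Planned markers of other cell types are given by signal. The green-cell genes LHCB4.1 and RCA had signals of 85.7 and 152 on day 1 and 71.6 and 93.6 on day 7, the secondary-wall gene IRX10 39.7 and 66.9 on those days, and the root-hair gene EXPA7 was below the floor on day 1 and at 28.9 on day 7.

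The low-oxygen genes, higher on day 3 as a group, are the first pattern weighed. A brightness-dependent shift of the day 3 array is argued against by the random lists of the same brightness, at -0.10 to 0.28 beside their median log2 ratio of 2.12. After quantile normalization the median was 1.96, with random lists between -0.22 and 0.16. Given the first ranking little else was possible, so this adds little. The 17 genes that went up and then down share the day 3 array, and an error common to 1 function is not expected from probe brightness. Oxygen shortage in the flask and oxygen shortage while the day 3 cells were being collected cannot be told apart, since there is 1 day 3 sample. Either may lie behind the pattern, and a second culture collected apart would be needed.

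The second pattern is the lower signal of ribosomal protein genes on day 7. These genes are bright, so a compression of bright signals could lower them, but after quantile normalization the median was still -1.26, with random lists of the same brightness between -0.47 and -0.04. With arrays scaled to the hybridisation controls, a shift by a constant, the upper quartile of the genes was -0.92 and the median -1.23. By that reference the genes were still lower on day 7. The scaling was chosen after the results had been seen and its shift was small beside the medians. Little else was possible, so it is no test of the overall scaling of the day 7 array. A candidate biological explanation is that cells make fewer ribosomes late in the passage, and the lower assembly factors and RNA polymerase subunits are consistent with it, though found in the same arrays. It was not tested, and the making of ribosomes was not measured here.

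The third pattern is the higher signal of mitochondrion-encoded genes on day 5. More organelle RNA of every kind is argued against by the plastid's genes for gene expression, whose median was -0.60, although the plastid's photosynthesis genes, at 0.62, went with it. More degraded RNA stays open, since the median log2 change of the 3' to 5' ratios was 0.10 from day 3 to day 5 but -0.29 from day 1, when the genes were low as well. A joint increase of the nuclear tricarboxylic acid cycle genes is argued against by their median of -0.40. A greater mitochondrial share of the RNA, longer poly(A) tails on these transcripts or the nuclear copy of the mitochondrial genome may each stay open, untested.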
